A study of Homo sapiens with 6 samples.

How the data were processed

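The series profiled where the zinc-finger transcription factor ZIC2 binds chromatin in H1 cells, an established human embryonic stem cell line (also named WA01), with and without the zinc-finger protein ZNF263. The assay was CUT&Tag, in which a transposase tethered to an antibody cuts and tags the DNA next to the bound protein in permeabilised nuclei, so that sequenced fragments mark binding sites. Per the labels, the 6 libraries were 2 anti-ZIC2 libraries of wild-type cells (WT), 2 anti-ZIC2 libraries of cells with a ZNF263 knockout made with Cas9, which the labels call homogeneous (KO), and 1 normal rabbit IgG library of each genotype. The labels number the ZIC2 replicates but do not say whether they came from separate cultures.

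The authors deposited 2 lists of ZIC2 peaks, 1 per genotype. Each list has 3 columns without a header, which hold the chromosome, the start and the end of each peak. The files hold no height, score, fold enrichment, p-value or read count for a peak, and no values per library. Bowtie2, Picard and the genome build hg19 are named in the submitters' processing notes, and the contig names in the lists are those of hg19. The peak caller, its threshold, the use made of the IgG libraries and the way the 2 replicates were combined are not given in the sources used here. Sequencing depth is therefore unknown, and the lists carry no replicate error. Only 1 list stands for each genotype, so no test between genotypes with replicates was possible, and a region missing from a list was not called there, which is not a measured loss of signal. The IgG libraries were not analysed here, and no background level could be set beside the ZIC2 lists.

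Lists were read with Python 3.11.15 and pandas 2.3.3. Statistics used numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6. Regions of the lists were called shared where they overlapped by at least 1 bp, and WT-only or KO-only otherwise. Shares of regions are given with exact Clopper-Pearson 95% binomial intervals, and numbers of regions with exact Poisson intervals. Both cover counting error only and treat regions as independent, which neighbouring regions are not. The overlap was compared with 1000 random placements of the KO regions on their own chromosomes, up to the last region end of either list, with unsequenced gaps not masked. Median widths were compared with two-sided permutation tests of 100000 resamples. The share of each list on each of 23 chromosomes (1 to 22 and X) was compared with two-sided Fisher's exact tests, and p-values were adjusted by the Benjamini-Hochberg method. Local density was counted as the number of other WT regions with a midpoint within 500 kb, and WT regions were parted into 4 groups by its quartiles. A logistic regression over WT regions had width, local density and chromosome 19 as terms, and was also fitted without width. Its intervals treat regions as independent as well. Windows of 1 Mb with at least 8 WT-only or KO-only regions were tested with exact binomial tests against the genome-wide KO-only share. Coordinates are hg19, counted from 1. The routines were tested on simulated data made from 16040 regions. All 4000 simulated shared regions were recovered, the 1 chromosome given an excess of KO-only regions was called with 0 others, and 0 of 20 runs without an excess called any chromosome. Simulated shared regions had identical edges in both lists, so their recovery checks the code only. The chromosome check compared KO-only with WT-only regions drawn independently, with an excess larger than that seen for chromosome 19. It does not check the test on full lists, which share regions, or its power for a smaller excess.

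These tests, the alternatives and the rule for what is named were fixed before the data were examined, except where a later choice is stated. The local density groups, the logistic regression and the windows were added after seeing the data. The comparison of WT-only with KO-only widths and the counts of regions within 5 kb of the other list were not among the fixed tests either. The rule named genes with a peak near their start, and, with no annotation of the files' build, the 10 widest regions of each class by coordinates. The gene table at hand is of GRCh38, another build, so genes, promoters, gene lists (pluripotency, lineage, signalling and unrelated-tissue markers) and sequence motifs were not analysed here. The files give no score, so width took its place wherever a ranking was planned. The alternatives were other overlap rules, narrower sets by width, lists of equal length, autosomes only, and joining regions within 1 kb.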

Results

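ZIC2 binding was mapped by CUT&Tag in wild-type H1 human embryonic stem cells (2 libraries) and in ZNF263-knockout H1 cells (2 libraries), with 1 IgG library per genotype. ZIC2 is a zinc-finger transcription factor of the ZIC family, expressed in pluripotent and early neural cells, and ZNF263 is a zinc-finger protein that binds DNA. The deposited data are 1 list of ZIC2-bound regions per genotype on hg19, without heights or read counts, so the values below have no replicate error and the read depth behind them is unknown. The comparison asks how the set of ZIC2-bound regions differed when ZNF263 was absent.

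Fewer ZIC2 regions were called in the knockout. The WT list held 12966 regions (95% Poisson interval 12744 to 13191) and the KO list 7231 (7065 to 7400), which is 55.8 KO regions per 100 WT regions. The WT regions covered 4346 kb and the KO regions 2898 kb, or 66.7% of the WT length, since KO regions were wider on average (401 bp against 335 bp). This does not mean that regions widened in KO. Shared regions, with a mean of 506 bp in either list, made up 57.0% of the KO list and 31.8% of the WT list. Of the WT regions, 4120 were also called in KO, which is 31.8% (30.97 to 32.6), and 8846 (68.2%, 67.4 to 69.0) were not. Of the KO regions, 3111 (43.0%, 41.9 to 44.2) were not in the WT list, so WT-only regions outnumbered KO-only regions by 2.84 to 1. The 2 lists together made 16077 different regions, of which 25.6% were in both.

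KO regions placed at random on their own chromosomes overlapped a WT region in 31.8 ± 5.36 cases (SD over 1000 placements) and in at most 56, against 4120 observed (one-sided permutation p = 0.001, the smallest these placements can give). With each region moved by no more than 50 kb, an alternative chosen after seeing the data, the mean was 127. Within 5 kb of a WT region lay 728 of the 3111 KO-only regions (23.4%), against 154 ± 12.2 for random placement and 343 ± 15.8 for placement within 50 kb (permutation p = 0.001 for both). Of the WT-only regions, 1056 (11.9%) lay within 5 kb of a KO region, against 250.0 ± 16.3 at random. All 4120 overlapping pairs had identical start and end positions in both lists, and no 2 neighbouring regions of the joint set were separated by 1 to 149 bp, whereas 578 pairs were separated by 150 to 299 bp and 46 pairs touched. The width of a shared region is thus 1 value common to both lists and not a measurement of each genotype. These values argue against 2 lists called separately and point to selection from 1 joint set of regions. The rule of that selection is not given in the sources used here. Random placement is then not a fair reference for the overlap or for the counts within 5 kb, and no conclusion is drawn from these comparisons. The shared, WT-only and KO-only shares depend on the rule.

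Regions called in both genotypes were the wide ones. Shared regions had a median width of 460 bp, against 181 bp for WT-only and 167 bp for KO-only regions. The differences of 279 bp and 293 bp were each larger than in all 100000 permutations (two-sided permutation test, p = 1e-05, the smallest these resamples can give, adjusted p = 1.5e-05 over 3 comparisons). A shared region was wider than a WT-only region in 84.4% of pairs. WT-only and KO-only regions differed by 14 bp in the median (permutation p = 0.00095), and a WT-only region was the wider in 51.2% of pairs, but the mean width (256 bp against 261 bp) and the upper quartile (298 bp against 315 bp) were larger for KO-only regions. The minimum width of 150 bp was held by 39.6% of WT-only, 43.8% of KO-only and 0.34% of shared regions. Because edges are common to both lists, a region may be wide because it had signal in both genotypes. These tests therefore cannot tell whether width preceded being called in both.

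The share of WT regions not called in KO was lower in each wider class of regions. It was 99.6% among WT regions of 150 bp (99.3 to 99.8, n = 3513), 69.9% from 201 to 300 bp (68.1 to 71.6), 44.4% from 401 to 600 bp (42.3 to 46.6) and 15.1% above 1000 bp (10.5 to 20.8, n = 205). The share of KO regions not called in WT was 99.0% at 150 bp, 38.5% from 201 to 300 bp, 21.4% from 401 to 600 bp, 9.42% from 801 to 1000 bp (6.69 to 12.8, n = 382) and 12.1% above 1000 bp (7.92 to 17.5, n = 198). WT-only regions outnumbered KO-only regions in each width class, by 3.70 to 1 from 201 to 300 bp and by 1.29 to 1 above 1000 bp. In that widest class the KO-only share of regions found in 1 list was 43.6% (30.3 to 57.7), an interval that includes equal numbers.

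**Figure D1:**
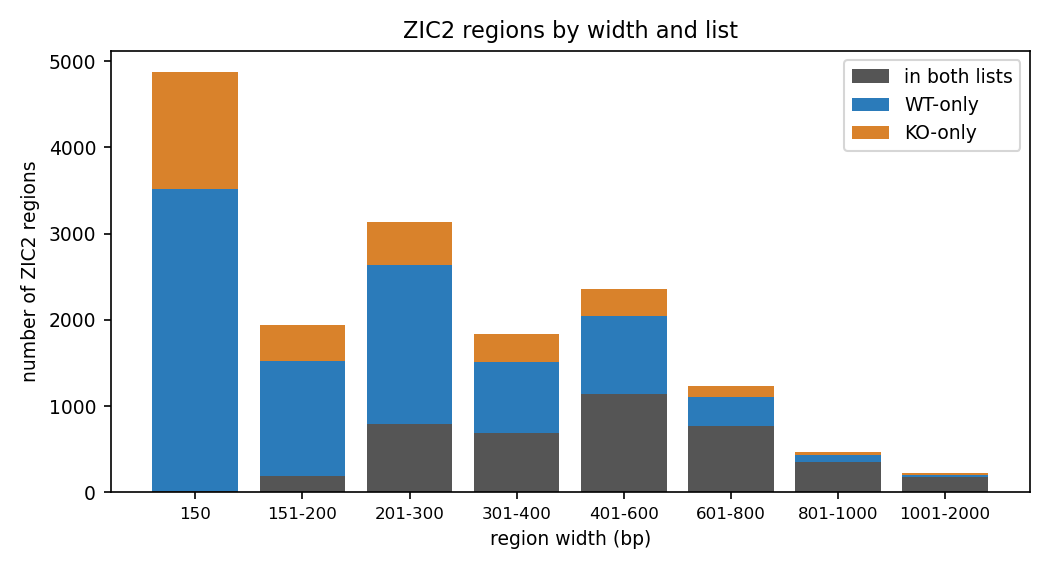
Number of ZIC2 regions (vertical axis) by region width in bp (horizontal axis), stacked as regions in both lists (grey), WT-only (blue) and KO-only (orange). Of the 4877 regions of 150 bp, 14 were in both lists, whereas 174 of the 229 regions above 1000 bp were.

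The widest regions of each class were named by position. The widest shared regions lay on chromosome 3 from 32884350 to 32886016 (1667 bp) and from 32821653 to 32823310 (1658 bp), and on chromosome 12 from 6960551 to 6962170 (1620 bp). The fourth was on the unplaced contig Un_gl000220 from 6839 to 8340 (1502 bp), a contig that carries ribosomal RNA gene sequence. The widest regions called in WT but not in KO were on chromosome 16 from 89631178 to 89632603 (1426 bp), chromosome 12 from 89746635 to 89747991 (1357 bp), chromosome 15 from 73075781 to 73077118 (1338 bp) and chromosome 6 from 99872698 to 99873976 (1279 bp). The widest regions called in KO but not in WT were on chromosome 19 from 18808718 to 18810191 (1474 bp), chromosome 11 from 63685709 to 63687081 (1373 bp), chromosome 19 from 35738741 to 35740023 (1283 bp) and chromosome 2 from 48010124 to 48011366 (1243 bp). Among the 10 widest of each class, 3 KO-only, 0 WT-only and 1 shared region were on chromosome 19. The genes at these positions were not analysed here.

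WT regions on chromosome 19 were called again in KO more often than those on other chromosomes. The share was 48.0% there (44.7 to 51.4, 417 of 868), 38.5% on chromosome 16 (34.4 to 42.7) and 37.7% on chromosome 17 (34.3 to 41.3). It was 21.4% on chromosome 13 (16.5 to 27.0), 23.4% on chromosome X (17.7 to 29.9) and 25.0% on chromosome 4 (21.3 to 29.0). Across the 23 chromosomes, the share kept rose with the number of WT regions per Mb (Pearson r = 0.91, permutation p = 1e-05, the smallest these resamples can give, and Spearman rho = 0.83, p = 2e-05). Without chromosomes 17 and 19, the farthest from the median density, r was 0.82 (permutation p = 1e-05). With local density as a covariate in a logistic regression over WT regions, the odds ratio for chromosome 19 was 1.37 (95% interval 1.18 to 1.59), and with region width added it was 1.17 (0.978 to 1.40), an interval that includes 1. Chromosomes are not replicates, and this relation was computed after seeing the data.

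**Figure D2:**
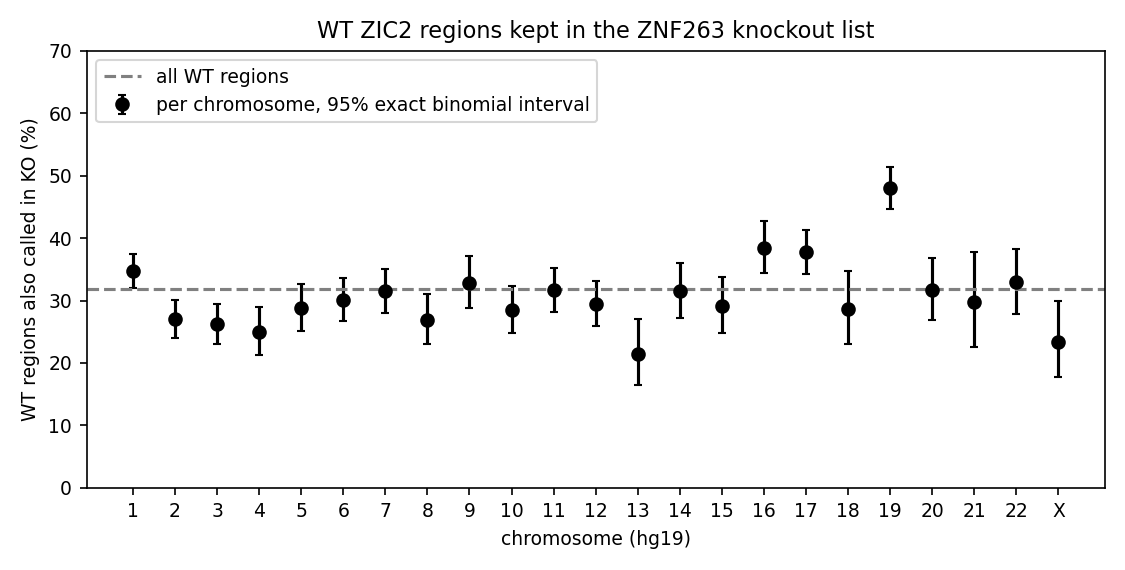
Percent of WT ZIC2 regions also called in KO (vertical axis) for each hg19 chromosome (horizontal axis). Points are the share per chromosome, bars are exact 95% binomial intervals and the dashed line is the share over all WT regions (31.8%). Chromosome 19 stands highest at 48.0% and chromosome 13 lowest at 21.4%.

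Chromosome 19 also held a larger part of the KO list, with 616 regions (8.52%), than of the WT list, with 868 regions (6.69%). The odds ratio was 1.30 (Fisher's exact test, two-sided, adjusted p = 5.92e-05 over 23 chromosomes), and no other chromosome passed the threshold. The lowest unadjusted p of Fisher's exact test among the others was 0.0175 for chromosome X (odds ratio 0.73, adjusted p = 0.201). The lists share 4120 regions, so this test does not compare independent sets. Chromosome 19 held 417 shared, 451 WT-only and 199 KO-only regions. Shared regions made up 57.0% of the KO list and 31.8% of the WT list. Part of the larger KO share thus follows from the many shared regions on this chromosome. Between KO-only and WT-only regions, which share none, the odds ratio for chromosome 19 was 1.27 and missed the threshold (Fisher's exact test, adjusted p = 0.153). Against a WT list limited to its 7231 widest regions it was 1.01 (Fisher's exact test, adjusted p = 1), but selecting WT regions by width favours shared regions and so draws the lists together by construction.

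WT regions in dense surroundings were called again in KO more often than isolated ones, also within chromosomes. Over all chromosomes, WT regions with at most 4 other WT regions within 500 kb were called again in KO in 21.96% of cases (20.7 to 23.3, n = 3958), and those with 14 to 41 others in 42.3% (40.5 to 44.0, n = 3024). Median width also rose between these groups, from 204 bp to 297 bp. In the logistic regression over 12937 WT regions with width and density, the odds of being called in KO rose 5.30-fold per doubling of width (95% interval 4.99 to 5.63) and 1.26-fold per doubling of local density plus 1 (1.20 to 1.32). Width is a value common to both lists, so the factor for width is not that of a property measured in WT alone. Without width, the factor for density was 1.37 (1.32 to 1.42), and with each chromosome as a term, a fit added after seeing the data, it was 1.35 (1.29 to 1.40). Fitted alone, 22 of the 23 chromosomes had a factor above 1, with an interval above 1 on 17. On chromosome 19 it was 1.08 (0.909 to 1.28), and on chromosome 13 it was 0.84 (0.618 to 1.15). The densest 1 Mb window, on chromosome 19 from 49000001 to 50000000, held 47 regions, of which 20 were shared, 15 WT-only and 12 KO-only. Next was the window from 46000001 to 47000000 on the same chromosome, with 45 regions in equal parts of 15. Dense windows of chromosome 19 differed in their make-up, with 23 WT-only and 4 KO-only regions from 1000001 to 2000000, 25 and 4 from 17000001 to 18000000, 14 and 9 from 45000001 to 46000000, and 17 and 7 from 50000001 to 51000000. The window with the lowest p, from 2000001 to 3000000 on this chromosome, held 6 WT-only and 12 KO-only regions. Of the 468 windows tested, 0 departed from the genome-wide KO-only share of 26.0% after adjustment (exact binomial test, lowest adjusted p = 0.127). At an unadjusted p under 0.05 there were 23. Exact tests on few regions pass this threshold by chance less often than its nominal rate. Whether 23 is more than chance gives was not tested.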

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

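Direction held under every setting that was run, with fewer KO than WT regions, except with lists of equal length. A larger part of the WT than of the KO regions was also found in 1 list. Where shared regions pair 1 to 1, this follows from the longer WT list and is no separate result. With lists of equal length the shares are equal by construction. Regions at or above the median width of both lists (276 bp) gave 72.7 KO regions per 100 WT regions, and regions wider than 150 bp, a setting chosen after seeing the data, gave 61.9. The percent of WT regions not called in KO was 56.6 for regions wider than 150 bp, 55.3 for regions at or above the median width of their own list, 63.5 when edges within 1 kb counted as shared, and 48.0 when the WT list was limited to as many regions as KO, by width. The percent of KO regions not called in WT was 29.8, 19.7, 36.6 and 48.0 under the same settings. The medians of the lists differ (250 bp for WT and 335 bp for KO). Shared regions between these widths were therefore cut from KO only and counted as not called there, which raises the 55.3. The shortened WT list likewise lost narrow shared regions, which then counted as not called in WT. Requiring 50% reciprocal overlap, or 25% of the shorter region, moved nothing, since all overlapping pairs have identical edges, and so tests nothing. Autosomes only left both shares and the ratio of list lengths within their intervals, and joining regions within 1 kb left that ratio within its interval. All 3 differences in median width kept their direction and call on autosomes. Chromosome 19 lost its call by Fisher's exact test (odds ratio 1.01, adjusted p = 1) against the shortened WT list, which favours shared regions by construction, and between KO-only and WT-only regions (odds ratio 1.27, adjusted p = 0.153, chosen after seeing the data), which left 0 chromosomes called in each. Its adjusted p was 0.000174 with regions joined and 0.0107 for regions wider than 150 bp. The cause of the second loss was not tested. No paired analysis was possible because the 2 replicates of each genotype stand behind 1 list, and for the same reason no replicate was left out. Alternatives for promoters, gene lists and motifs were not run, for want of an annotation of the same build. Depth limits what can be said, since weak regions cannot be told from uncalled ones without read counts.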

Other observations

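The tests in this part were not among those fixed before the data were examined. For some, the outcome that each explanation predicts was written before the test was run. These are the tests of chromosome 19 against strata of width and density, of its 2 sides, and of whether neighbouring regions are of the same class. Chromosome 19 itself was picked after its excess was seen. The other tests were chosen after the result was seen. Contigs outside the assembled chromosomes held 24 WT and 23 KO regions on 6 contigs. Of these, 16 regions lay on Un_gl000220, which carries ribosomal RNA gene sequence, with 7 shared, 3 WT-only and 6 KO-only, so that this contig had more KO than WT regions.

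The KO list is shorter than the WT list. Lower sensitivity in the KO libraries alone would leave few regions called only in KO, but these made up 43.0% of the KO list. Chance calls near the threshold at equal sensitivity would give equal numbers in both directions, whereas KO-only regions were 26.0% of regions found in 1 list. Since shared regions pair 1 to 1, that share restates the shorter KO list and is not separate evidence. The combination of lower KO sensitivity and calls near the threshold stays open: 18.0% of WT regions of at least 800 bp were not called in KO, against 95.9% of those under 200 bp, but edges common to both lists make width a joint value, and a region with signal in both genotypes may be wide for that reason under any explanation. Loss of ZNF263 stays open as well and cannot be told apart from a difference between libraries, since there is 1 peak list per genotype.

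Chromosome 19 holds a larger share of the KO list, and region width and local density are a candidate explanation. For WT regions kept in KO, the odds ratio for chromosome 19 was 2.10 without covariates and 1.37 (95% interval 1.18 to 1.59) with density alone as a covariate. That fit treats regions as independent and gives density 1 common slope, whereas the factor for density on chromosome 19 alone was 1.08 (0.909 to 1.28). Whether density is the whole cause therefore stays open. With width added, the odds ratio for chromosome 19 was 1.17 (0.978 to 1.40). Width is a joint value that goes with being called in both lists, so whether width accounts for the rest stays open. For KO-only against WT-only regions, the odds ratio within strata of width and density was 1.25 (1.04 to 1.51, and 1.01 to 1.57 when 1 Mb windows were resampled 500 times), close to 1.27 without strata. This argues against width and density, as grouped here, as the whole cause there. The lower bound is near 1 on a chromosome picked for its excess, and the excess itself missed the threshold (Fisher's exact test, adjusted p = 0.153). The densest group spans 14 to 41 other WT regions, so differences in density within it stay open. A gain of the whole chromosome in the KO cells cannot be told apart from no gain: KO-only regions were 27.7% (22.7 to 33.2) of regions found in 1 list before the chromosome's largest gap (24258861 to 28284071) and 33.1% (28.2 to 38.2) after it, against 25.7% on the other chromosomes, so the interval excludes that level on 1 side only.

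One hypothesis was that regions lost and gained in KO fall into separate stretches of the genome. Neighbouring regions found in 1 list were of the same class in 7457 of 11912 cases (62.6%), against 7337 ± 41.7 (SD, 61.6%) in 10000 permutations of the classes within chromosomes (two-sided p = 0.0044), a small excess. Permuting within the 4 groups of local density as well gave a mean of 7342 (permutation p = 0.0092), so density as grouped here accounts for little of it. The groups are coarse, and local density counts WT-only regions, whose class was permuted. A finer gradient of density therefore stays open. A second hypothesis, that KO-only regions are WT-only regions moved by under 1 kb, is argued against as an account of most of them: 281 of the 3111 KO-only regions (9.03%, 8.05 to 10.1) had a WT-only region within 1 kb, and the 279 neighbouring pairs of the 2 classes at that distance compare with 261 ± 12.6 in the permutations (permutation p = 0.167). Moves within a shared region cannot be seen, since shared regions have the same edges in both lists.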
